A study of Mus musculus with 6 samples.

How the data were processed

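Gene expression was measured with Affymetrix arrays in sorted BDC2.5 CD4 T cells from NOD mice, in 3 groups of 2 arrays: PBS, anti-DEC205-BDC and anti-DCIR2-BDC. Per the labels' protocols, RNA was isolated with a PicoPure kit, and 5 ng of total RNA was amplified with a NuGen Ovation pico whole-transcriptome kit and labelled with biotin. Amplification from so little RNA can add noise, above all for dim probe sets. The deposited values are log2 expression per probe set, preprocessed by the authors with RMA in Partek, per the series' design text and the submitters' processing notes. RMA corrects background, equalises the distributions of the arrays and summarises probes, so a change shared by all genes cannot be seen. The version of Partek and the RMA settings are not given in the sources used here. The design text speaks of averaged values, but the deposited columns hold 1 array each, and these were used. The 35556 probe sets had values from 2.15 to 13.9, with 0 missing. The number of arrays limits the precision: the median 95% interval of a log2 change reached 0.388 to either side. The labels call the arrays of a group biological duplicates without saying how many mice gave each, so p-values of single genes measure the spread between these samples.

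The platform annotation named 23410 probe sets, of which 21789 had 1 gene symbol and 1621 several, and 12146 were unnamed here. Entrez identifiers matched 21698 of the single-symbol probe sets to RefSeq genes of GRCm38.p6, 91 did not match, and 0 symbols changed. Probe sets with several symbols or none were left out of the comparisons, as they cannot be assigned to 1 gene. For each of the 999 genes with several probe sets, the one with the highest mean over all 6 arrays was used, which left 19938 genes, with no filter on dim ones. Replicate arrays shared at most 18 identical values, so none was a copy of another.

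Groups were compared in limma 3.58.1 (R 4.3.3) with 1 mean per group over all 6 arrays, moderated variances with a trend on the mean, and Benjamini-Hochberg adjustment over all genes. The threshold was an adjusted p of 0.05, and tests were two-sided. Replicate numbers were not used as a block, since the labels do not say that equal numbers share a mouse, litter or day. The 28 gene lists, 18 of T cell functions and 10 of cell type markers, were tested with camera with a preset correlation of 0.01, adjusted over the lists. Camera sets the members of a list against other genes. With a preset correlation its p-values do not measure how a list varies between samples. The lists were tested again with an estimated correlation, with which all list calls were lost. For some lists, such as cell cycle, cytokine and interferon genes, the estimates (-0.0137, -0.0127 and -0.0205) lay below the preset. A higher correlation thus did not cost these lists their calls. Other estimates lay above the preset, at 0.158 for ribosome biogenesis, 0.196 for activation and 0.174 for amino acid and one-carbon genes. Those for naive and quiescent genes, glycolysis genes, T cell identity markers and cholesterol genes were 0.103, 0.101, 0.15 and 0.445. Calls of such lists with the preset thus assume a lower correlation than was estimated. Of the 418 members of the 28 lists 382 were measured. For the shared controls, 100 simulations drew unchanged groups against the PBS arrays.

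Genes were named by a rule: the 10 largest rises and 10 largest falls among genes that passed and whose arrays did not overlap between the groups. Symbols that start with Gm and a digit, LOC, Olfr, Vmn or Mir, or that end in Rik, and probe sets of several genes were left out. Where fewer than 5 passed in a direction, non-overlapping genes with a change of at least 2-fold and the smallest unadjusted p filled up to 5. Zbtb32, Ly75 and Clec4a4 were named in every comparison, as were up to 4 members of each list with the largest change, passing members first. Chance alone separates 2 arrays from 2 in 33.3% of genes, and 48.8%, 55.3% and 40.2% of genes were separated in the 3 comparisons in the order reported. Outside the rule, Cd3d, Cd3e, Cd3g after anti-DEC205-BDC, Cd247, Cst3, Cd68, Cd74, H2-Eb1, C1qa, Zbtb46, Mki67, Foxp3, Il4 and Il10, Bcl2l1, Dgka after anti-DEC205-BDC, Idi1 after anti-DCIR2-BDC, and Il2, Il3, Nr4a1 and Nr4a3 in comparisons whose rule did not name them were singled out after their values were seen.

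The comparison of groups was tested on simulated data of 19938 genes with 100 genes changed 2-fold and 100 changed 4-fold per comparison. For anti-DEC205-BDC against PBS it recovered 88% of 2-fold and 100% of 4-fold changes with 14 false calls, for anti-DCIR2-BDC against PBS 95% and 100% with 14, and for the antibodies against each other 89% and 100% with 15. Where fewer genes change, the adjustment is stricter, so the last shares do not carry over to the real arrays. There 4 genes passed between the antibodies, and Ccl1, 3.05-fold higher, did not (limma adjusted p = 0.0679). The alternatives were a replicate block, median centring, quantile normalization, leaving out the dimmest 30% or 50% of genes, the mean of probe sets, every probe set, no trend, a robust trend, only the 4 arrays compared, array weights, leaving out each array, a 2-fold minimum, an adjusted p of 0.10 for the overlap, the estimated correlation and, chosen after seeing the data, fry in place of camera. The lists, the naming rule and the other alternatives were fixed before the data were examined. With every probe set, each of the 35556 probe sets was its own row, and a named gene kept the probe set chosen for it. Its change thus stayed the same, while the variance trend and the adjustment ran over all rows. A loss there does not mean that another probe set of the gene disagreed.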

Results

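The series measured gene expression in BDC2.5 CD4 T cells taken from the spleens of female NOD mice aged 7 weeks. NOD is a mouse strain that develops autoimmune diabetes, and BDC2.5 is a T cell receptor specific for an antigen of the pancreatic beta cell. Mice that had received BDC2.5 T cells were injected with PBS, with 100 ng of an antibody against DEC205 carrying the BDC antigen (anti-DEC205-BDC), or with 100 ng of an antibody against DCIR2 carrying it (anti-DCIR2-BDC). DEC205 and DCIR2 are surface receptors of different dendritic cell types, and the antibodies deliver the antigen to those cells. The transferred cells were sorted as Thy1.1+CD4+ cells 14 h later. Each of the 3 groups had 2 arrays, labelled as biological duplicates and called here PBS, DEC205 and DCIR2 arrays 1 and 2, and their number limits the precision of every value. Medians of the 6 arrays lay between 5.43 and 5.56 on the log2 scale. Across probe sets, which are not independent replicates, arrays correlated at r = 0.974 within PBS, 0.974 within anti-DEC205-BDC and 0.982 within anti-DCIR2-BDC. Arrays of PBS and anti-DCIR2-BDC correlated at 0.940 to 0.947, those of PBS and anti-DEC205-BDC at 0.955 to 0.964, and those of the antibody groups at 0.971 to 0.980. DEC205 array 2 correlated better with DCIR2 arrays 1 and 2 (0.979 and 0.980) than with DEC205 array 1 (0.974). DEC205 array 1 correlated with DCIR2 arrays 1 and 2 at 0.971 each.

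The first comparison asked what anti-DEC205-BDC changed in the T cells against PBS. No group had an antibody without the antigen. In both comparisons against PBS, effects of the antigen and of the antibody itself therefore cannot be told apart. After anti-DEC205-BDC Il2, the T cell growth factor, rose 11.8-fold, from 5.20 ± 0.78 in PBS to 8.77 ± 0.45 (SD, n = 2, log2 values, limma adjusted p = 0.000512). Tnfrsf9, the costimulatory receptor 4-1BB, rose 8.82-fold (adjusted p = 0.000193), and Nr4a3, a nuclear receptor induced by T cell receptor signals, rose 6.87-fold (adjusted p = 0.000251). Il7r, the receptor chain for the survival cytokine IL-7, fell by 1.88 on the log2 scale (standard error 0.27, adjusted p = 0.00276), but did not pass with every probe set (adjusted p = 0.0543), range 0.000681 to 0.0543 over the alternatives. In all, 1763 of 19938 genes passed, 1060 upwards and 703 downwards, and 827 of them changed at least 2-fold. The count was 1013 without PBS array 1, 1131 without DEC205 array 1, 997 without DEC205 array 2 and 694 when every probe set was tested. With median centring 1186 genes were higher and 498 lower.

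The other genes with the largest rises were Cdca7 (log2 change 3.15), a MYC-responsive gene, Bcat1 (2.94), which starts the breakdown of branched-chain amino acids, and Mrto4 (2.84), a ribosome assembly factor. They were followed by the transcription factor Irf4 (2.70), the small nucleolar RNA Snora73b (2.61), the lipid transporter Mfsd2a (2.61) and the tRNA methyltransferase Mettl1 (2.58). The small nucleolar RNAs Snord61 (-3.89) and Snord35b (-2.02), Tmem71 (-2.12), St6galnac1 (mean level from 7.88 to 5.88) and AB124611 (-1.99) showed the largest falls. Il18r1, a chain of the IL-18 receptor (-1.97), the interferon-induced gene Rtp4 (-1.96), BC147527 (-1.88) and Ifi208 (-1.82) came next. The change of Snord61 was -2.23 without PBS array 1. It did not pass with every probe set (adjusted p = 0.134) or with a robust trend (0.19), range 0.000224 to 0.19 over the alternatives. Snord35b did not pass without PBS array 2 (adjusted p = 0.0959), without DEC205 array 1 (0.0905) or with every probe set (0.138), range 0.000534 to 0.138 over the alternatives. BC147527 did not pass without PBS array 2 (adjusted p = 0.0621), without DEC205 array 1 (0.0632) or with every probe set (0.12), range 0.00319 to 0.12 over the alternatives. Rtp4 did not pass with every probe set (adjusted p = 0.069), range 0.00135 to 0.069 over the alternatives. St6galnac1 did not pass with every probe set (adjusted p = 0.0921), range 0.000964 to 0.0921 over the alternatives.

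Of the lists fixed beforehand, ribosome biogenesis genes rose throughout (27 of 27 rose and 0 fell, or 27 and 0 adjusted over the list alone), led by Nhp2 (log2 change 2.18), Rrs1 (2.12), Nolc1 (1.99) and Mybbp1a (1.93). Ribosome biogenesis genes passed as a list (camera adjusted p = 4.25e-37, in the alternatives from 9.63e-38 to adjusted p = 0.0563 with an estimated correlation). Among T cell receptor-induced activation genes 15 of 24 rose and 0 fell, or 16 and 0 adjusted over the list alone, with Tnfrsf9 (3.14), Nr4a3 (2.78), Irf4 (2.70) and Nr4a1 (2.46) in front. Activation genes passed as a list (camera adjusted p = 2.11e-19, in the alternatives from 1.29e-19 to adjusted p = 0.102 with an estimated correlation). Of the cell cycle genes 16 of 34 rose and 0 fell, or 22 and 0 adjusted over the list alone. The replication licensing genes Mcm2 (1.81), Mcm3 (1.80) and Mcm6 (1.69) and the DNA methylation cofactor Uhrf1 (1.73) led them. Cell cycle genes passed as a list (camera adjusted p = 6.59e-14, in the alternatives from 1.84e-16 to adjusted p = 0.0563 with an estimated correlation). In the amino acid uptake and one-carbon list 10 of 15 rose and 0 fell, or 11 and 0 adjusted over the list alone, with the one-carbon enzymes Shmt2 (2.09) and Mthfd1 (1.99) and the amino acid transporter Slc7a5 (1.95) in front. Amino acid and one-carbon genes passed as a list (camera adjusted p = 7.85e-12, in the alternatives from 2.33e-12 to adjusted p = 0.106 with an estimated correlation). Of the glycolysis genes 8 of 13 rose and 0 fell, or 9 and 0 adjusted over the list alone, led by the lactate transporter Slc16a1 (1.88), Pgam1 (1.79) and Pgk1 (1.66). Glycolysis genes passed as a list (camera adjusted p = 3.25e-07, in the alternatives from 2.83e-07 to adjusted p = 0.112 with an estimated correlation). Pgk1 did not pass with every probe set (adjusted p = 0.0715), range 0.00154 to 0.0715 over the alternatives.

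Among cytokine and chemokine genes 8 of 23 rose and 1 fell, or 11 and 2 adjusted over the list alone. Il2 (log2 change 3.57), the chemokine gene Xcl1 (2.06), the inflammatory cytokine gene Tnf (1.77) and Ccl1 (1.64) led. Cytokine and chemokine genes passed as a list (camera adjusted p = 4.52e-08, in the alternatives from 1.64e-09 to adjusted p = 0.0563 with an estimated correlation). Naive and quiescent T cell genes went down (0 of 21 rose and 14 fell, or 0 and 18 adjusted over the list alone), with Il7r (-1.88), the egress receptor S1pr1 (-1.70), the glucose uptake inhibitor Txnip (-1.58) and Igfbp4 (-1.56) lowest. Naive and quiescent genes passed as a list (camera adjusted p = 6.59e-14, in the alternatives from 4.43e-16 to adjusted p = 0.0938 with an estimated correlation). Interferon response genes went down too (0 of 21 rose and 13 fell, or 0 and 14 adjusted over the list alone), led by Rtp4 (-1.96), Zbp1 (-1.55), Xaf1 (-1.46) and the transcription factor Irf7 (-1.41). Interferon response genes passed as a list (camera adjusted p = 8.59e-12, in the alternatives from 4.77e-13 to adjusted p = 0.0563 with an estimated correlation). Igfbp4 did not pass with every probe set (adjusted p = 0.0649), range 0.00144 to 0.0649 over the alternatives. Txnip did not pass with every probe set (adjusted p = 0.0545), range 0.000882 to 0.0545 over the alternatives. Xaf1 did not pass with every probe set (adjusted p = 0.0537), range 0.0016 to 0.0537 over the alternatives. Il7r did not pass with every probe set (adjusted p = 0.0543), range 0.000681 to 0.0543 over the alternatives, nor did Rtp4 with every probe set (adjusted p = 0.069), range 0.00135 to 0.069 over the alternatives.

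In the 3 other lists that passed, few members passed by themselves. Of the cholesterol synthesis genes 1 of 16 rose and 0 fell, or 3 and 0 adjusted over the list alone, the 1 being Idi1 (log2 change 1.02) (camera adjusted p = 0.0096, in the alternatives from 0.00134 to adjusted p = 0.521 with an estimated correlation). This list did not pass without PBS array 1 (adjusted p = 0.0941), without DEC205 array 2 (0.107), without the dimmest 50% of genes (0.0678) or by fry (0.31). Idi1 did not pass with every probe set (adjusted p = 0.0543), range 0.00323 to 0.0543 over the alternatives. Of the T cell identity markers 1 of 12 rose and 1 fell, or 1 and 5 adjusted over the list alone. T cell identity markers passed downwards as a list (camera adjusted p = 0.0236, in the alternatives from 0.00187 to adjusted p = 0.408 with an estimated correlation). Its members that passed were the kinase Zap70, which rose (1.15), and the receptor adaptor Trat1, which fell (-1.04). The list did not pass without PBS array 2 (adjusted p = 0.174), without DEC205 array 2 (0.0882), without the dimmest 30% of genes (0.0533), without the dimmest 50% of genes (0.0579), with no trend (0.0526) or by fry (0.115). Zap70 did not pass without DEC205 array 2 (adjusted p = 0.0566) or with every probe set (0.0709), range 0.00148 to 0.0709 over the alternatives. Trat1 did not pass without PBS array 1 (adjusted p = 0.153), without DEC205 array 2 (0.143) or with every probe set (0.132), range 0.0124 to 0.153 over the alternatives. Of the natural killer cell markers 0 of 9 rose and 2 fell, or 0 and 3 adjusted over the list alone, the lectin receptor chain Klrd1 (-1.54) and the pore-forming protein Prf1 (-0.97) (camera adjusted p = 0.0236, in the alternatives from 0.00908 to adjusted p = 0.229 with an estimated correlation). The list did not pass without PBS array 1 (adjusted p = 0.0561), without DEC205 array 1 (0.0607) or without the dimmest 30% of genes (0.0533). Klrd1 (-0.92 without DEC205 array 2) did not pass without PBS array 2 (adjusted p = 0.0711) or with every probe set (0.126), range 0.0017 to 0.126 over the alternatives. Prf1 did not pass without DEC205 array 1 (adjusted p = 0.0648) or with every probe set (0.0566), range 0.00572 to 0.0648 over the alternatives.

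The remaining T cell lists did not pass by camera. Of the inhibitory receptors 4 of 14 rose and 1 fell, or 4 and 2 adjusted over the list alone, led by Cd200 (log2 change 2.23) and Lag3 (1.11) (camera adjusted p = 0.077). That list passed without PBS array 1 (adjusted p = 0.0452), without DEC205 array 2 (0.0379), without the dimmest 30% of genes (0.00675), without the dimmest 50% of genes (0.00852) or by fry (0.00824), range 0.00675 to 0.305 over the alternatives. Of the anergy genes 4 of 18 rose and 1 fell, or 4 and 2 adjusted over the list alone, led by the transcription factor Egr2 (1.61) and the diacylglycerol kinase Dgka (-1.21) (adjusted p = 0.964), with a median of -0.24 against a mean of 0.04. Of the Th1 and cytotoxic effector genes 3 of 14 rose and 1 fell, or 4 and 1 adjusted over the list alone, led by Il18r1 (-1.97) and Tnf (1.77) (adjusted p = 0.077). That list passed without PBS array 1 (adjusted p = 0.02) or without DEC205 array 2 (0.0115), range 0.0115 to 0.531 over the alternatives. Of the regulatory T cell genes 2 of 15 rose and 0 fell, or 2 and 0 adjusted over the list alone, led by the IL-2 receptor chain Il2ra (1.69) (adjusted p = 0.193). Foxp3, their transcription factor, was at -0.32 (adjusted p = 0.44). Of the Th2 genes 1 of 7 rose and 0 fell, or 1 and 1 adjusted over the list alone (adjusted p = 0.964), the 1 being the chemokine receptor Ccr8 (1.19), and camera put the list below other genes while its median was 0.14 and its mean 0.00145. Ccr8 did not pass without PBS array 1 (adjusted p = 0.218), without PBS array 2 (0.0757), without DEC205 array 1 (0.0665), without DEC205 array 2 (0.203), with every probe set (0.215), with no trend (0.0679), with a robust trend (0.0543) or with array weights (0.0571), range 0.00915 to 0.218 over the alternatives.

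In the Th17 list 0 of 6 rose and 0 fell, or 1 and 0 adjusted over the list alone, with 1 gene, Ahr (log2 change 0.60), at an unadjusted p under 0.05 (camera adjusted p = 0.964, median -0.05, mean 0.06). Ahr passed with quantile normalization (adjusted p = 0.04) or without the dimmest 50% of genes (0.0496), range 0.04 to 0.282 over the alternatives. Of the T follicular helper genes 3 of 13 rose and 2 fell, or 5 and 3 adjusted over the list alone, led by Cd200 (2.23) and the B cell coactivator Pou2af1 (1.88) (adjusted p = 0.309). Of the apoptosis genes 2 of 13 rose and 1 fell, or 5 and 3 adjusted over the list alone, led by the stress-inducible Gadd45b (1.71) (adjusted p = 0.424). Of the immediate-early stress genes 3 of 14 rose and 2 fell, or 3 and 4 adjusted over the list alone, led by the chaperone Hsph1 (1.55) and the transcription factor Jun (-1.24) (adjusted p = 0.751). Hsph1 (0.85 without PBS array 2) did not pass without PBS array 2 (adjusted p = 0.129), without DEC205 array 1 (0.139), without DEC205 array 2 (0.0571), without DCIR2 array 1 (0.0567), without DCIR2 array 2 (0.0568), with quantile normalization (0.0624), with every probe set (0.187), with no trend (0.0527) or with only the 4 arrays compared (0.0585), range 0.00312 to 0.187 over the alternatives. Gadd45b did not pass with every probe set (adjusted p = 0.0857), range 0.00231 to 0.0857 over the alternatives. Jun did not pass with every probe set (adjusted p = 0.0643), range 0.00191 to 0.0643 over the alternatives. Markers of other cells stood as follows, with counts adjusted over the list alone that were the same as those over all genes. In the lists of 4 CD8 T cell, 13 B cell, 9 neutrophil and 6 erythroid markers 0 rose and 0 fell in limma (1, 3, 0 and 1 at an unadjusted p under 0.05, all lower, and camera adjusted p = 0.257, 0.45, 0.964 and 0.964). In those of 7 plasma cell, 16 dendritic cell, 13 macrophage and monocyte and 8 stromal and endothelial markers 0 rose and 1 fell in each (adjusted p = 0.179, 0.805, 0.239 and 0.446). The CD8 T cell list passed without PBS array 2 (adjusted p = 0.0456), range 0.0456 to 0.85 over the alternatives. The B cell list had a median of 0.01 and a mean of -0.07 and the neutrophil list a median of -0.07 and a mean of -0.00646, and camera put the former below and the latter above other genes.

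Among the genes of interest, Zbtb32, a transcription repressor that the study picked out on these samples, had a log2 change of 0.42 with a 95% interval of -0.07 to 0.91 (adjusted p = 0.322). Ly75, which encodes DEC205 and is the dendritic cell marker that fell, changed by -0.75 in the T cells (adjusted p = 0.0297) from a PBS level at percentile 82.3 among genes, and did not pass without any 1 of the 6 arrays (adjusted p = 0.0562 to 0.133), with every probe set (0.0903) or with only the 4 arrays compared (0.0569), range 0.0146 to 0.133 over the alternatives. Clec4a4, which encodes DCIR2, had a PBS mean of 3.42, at percentile 3.39, and a change of 0.10 (adjusted p = 0.756).

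The second comparison put the same question for anti-DCIR2-BDC. After anti-DCIR2-BDC cytokine genes were in front: Il3, which encodes a growth factor for myeloid cells, rose 68.0-fold from 3.76 ± 0.13 in PBS to 9.84 ± 0.69 (SD, n = 2, log2 values, limma adjusted p = 4.81e-05). Its PBS level lay at percentile 6.56 among genes, close to the floor of the arrays, where changes are understated. Il2 rose 39.8-fold (adjusted p = 3.39e-05), and Irf4 rose 11.5-fold (adjusted p = 3e-05). Zbtb32, chosen by the study on these samples, rose 4.89-fold, from 6.12 ± 0.13 to 8.41 ± 0.35 (SD, n = 2, adjusted p = 9.77e-05). In all, 3568 genes passed, 2008 upwards and 1560 downwards, and 1839 of them changed at least 2-fold. The count was 2285 without DCIR2 array 1 and 2090 without DCIR2 array 2. With median centring 2394 genes were higher and 1173 lower.

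The other large rises were those of Bcat1 (log2 change 4.09), Utf1 (3.85), Cdca7 (3.80), Mrto4 (3.43), the chemokine genes Xcl1 (3.33) and Ccl1 (3.25), and Mfsd2a (3.33). The largest falls were those of Snord61 (-3.26), Il18r1 (-2.81), Tmem71 (-2.77), Gmfg (-2.65) and Il7r (-2.64). Next to them stood the interferon-induced genes Samd9l (-2.64) and Ifi203 (-2.59), Klrd1 (-2.62), Tcp11l2 (-2.62) and Rasgrp2 (-2.56), which activates the GTPase Rap1 in T cells. The other probe set of Gmfg changed by -0.18, so its probe sets disagreed. The change of Snord61 was -1.60 without PBS array 1 and -4.92 without PBS array 2. It did not pass without DCIR2 array 1 (adjusted p = 0.153), without DCIR2 array 2 (0.0511), with every probe set (0.125) or with a robust trend (0.194), range 0.000159 to 0.194 over the alternatives. Ly75 fell by 1.10 on the log2 scale (adjusted p = 0.00182), and Clec4a4 had a change of 0.14 (adjusted p = 0.591).

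**Figure D1:**
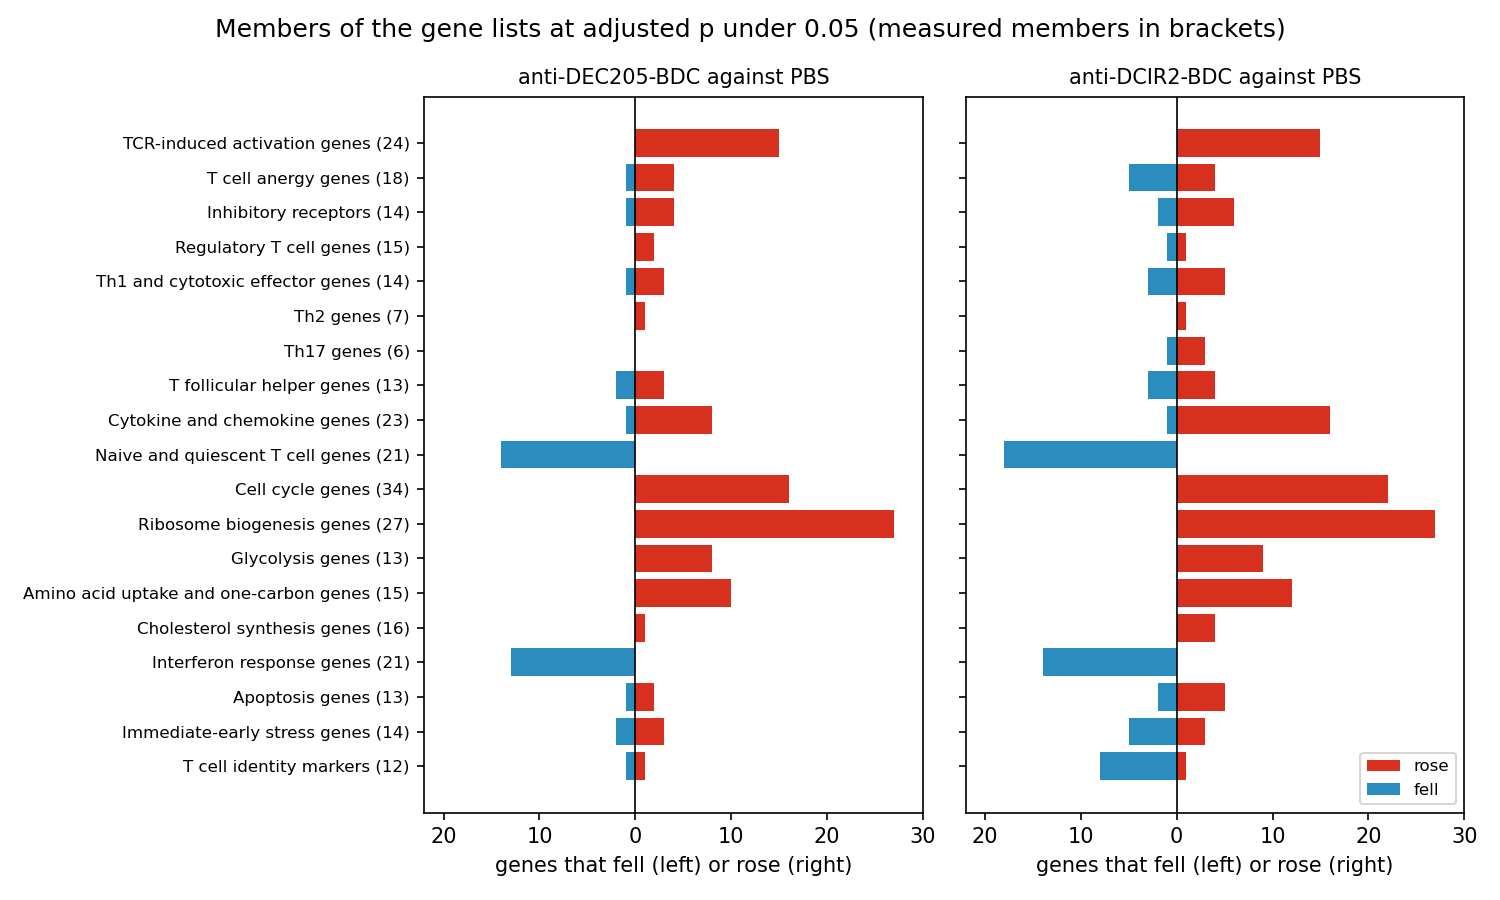
Number of members that rose (right) or fell (left) at an adjusted p under 0.05 after each antibody, with measured members in brackets. Shown are the 18 lists of T cell functions and the T cell identity markers. All 27 ribosome biogenesis genes rose after both antibodies.

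All measured ribosome biogenesis genes rose here as well (27 of 27 rose and 0 fell, or 27 and 0 adjusted over the list alone), led by Nolc1 (log2 change 2.59), Nhp2 (2.52), Mybbp1a (2.50) and Polr1b (2.49), a subunit of RNA polymerase I. Ribosome biogenesis genes passed as a list (camera adjusted p = 6.91e-33, in the alternatives from 1.28e-33 to adjusted p = 0.0625 with an estimated correlation). Of the cell cycle genes 22 of 34 rose and 0 fell, or 23 and 0 adjusted over the list alone, led by Mcm2 (2.58), Mcm3 (2.40) and Mcm6 (2.29). Cell cycle genes passed as a list (camera adjusted p = 4.9e-16, in the alternatives from 1.04e-16 to adjusted p = 0.0574 with an estimated correlation). Mki67, a proliferation marker, had a change of 0.08 (adjusted p = 0.87). Among the activation genes 15 of 24 rose and 0 fell, or 17 and 0 adjusted over the list alone, led by Irf4 (3.52), Nr4a3 (2.82), Myc (2.74) and Tnfrsf4 (2.64), the gene of OX40. Activation genes passed as a list (camera adjusted p = 1.11e-14, in the alternatives from 4.82e-15 to adjusted p = 0.113 with an estimated correlation). In the amino acid uptake and one-carbon list 12 of 15 rose and 0 fell, or 13 and 0 adjusted over the list alone, with Mthfd1 (2.71), Shmt2 (2.67) and the serine synthesis enzyme Psat1 (2.63) in front. Amino acid and one-carbon genes passed as a list (camera adjusted p = 5.95e-13, in the alternatives from 1.98e-13 to adjusted p = 0.102 with an estimated correlation). Of the glycolysis genes 9 of 13 rose and 0 fell, or 10 and 1 adjusted over the list alone, led by the hexokinase Hk2 (2.26), Slc16a1 (2.18) and Pgam1 (2.14). Glycolysis genes passed as a list (camera adjusted p = 1.9e-08, in the alternatives from 1.18e-08 to adjusted p = 0.102 with an estimated correlation).

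Of the cytokine and chemokine genes 16 of 23 rose and 1 fell, or 16 and 1 adjusted over the list alone, with Il3 (log2 change 6.09), Il2 (5.31), Xcl1 (3.33) and Ccl1 (3.25) in front. Cytokine and chemokine genes passed as a list (camera adjusted p = 5.01e-10, in the alternatives from 2.38e-11 to adjusted p = 0.0574 with an estimated correlation). Il4 and Il10, the genes of cytokines of Th2 and regulatory cells, had changes of 0.14 and 0.25 (adjusted p = 0.618 and 0.504). Naive and quiescent genes went down (0 of 21 rose and 18 fell, or 1 and 18 adjusted over the list alone), led by Il7r (-2.64), Txnip (-2.40), Igfbp4 (-2.07) and S1pr1 (-2.04). Naive and quiescent genes passed as a list (camera adjusted p = 5.85e-13, in the alternatives from 1.88e-16 to adjusted p = 0.102 with an estimated correlation). Interferon response genes did so as well (0 of 21 rose and 14 fell, or 1 and 16 adjusted over the list alone), led by Zbp1 (-2.05), the RNA sensor Ddx58 (-1.99) and Rtp4 (-1.79). Interferon response genes passed as a list (camera adjusted p = 1e-09, in the alternatives from 1.29e-11 to adjusted p = 0.0574 with an estimated correlation). Among T cell identity markers 1 of 12 rose and 8 fell, or 1 and 9 adjusted over the list alone. Trat1 (-1.72), the T cell receptor complex gene Cd3g (-1.24) and the adhesion receptor Cd2 (-1.15) fell, and Zap70 rose (1.31). T cell identity markers passed as a list (camera adjusted p = 0.000116, in the alternatives from 5.23e-07 to adjusted p = 0.212 with an estimated correlation).

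Inhibitory receptors passed as a list upwards (6 of 14 rose and 2 fell, or 6 and 3 adjusted over the list alone), led by Cd200 (log2 change 2.94) and Lag3 (1.34) (camera adjusted p = 0.045, in the alternatives from 0.00332 to adjusted p = 0.219 with an estimated correlation). The list did not pass without PBS array 2 (adjusted p = 0.08), without DCIR2 array 2 (0.0674), with median centring (0.114) or with quantile normalization (0.174). Natural killer cell markers passed downwards (0 of 9 rose and 4 fell, or 0 and 4 adjusted over the list alone), led by Klrd1 (-2.62) and the granzyme gene Gzma (-1.15) (camera adjusted p = 0.0236, in the alternatives from 0.00802 to adjusted p = 0.212 with an estimated correlation), though not without the dimmest 30% of genes (adjusted p = 0.069). The change of Gzma was -0.55 without PBS array 1 and -1.74 without PBS array 2. It did not pass without PBS array 1 (adjusted p = 0.0735), without DCIR2 array 1 (0.0747), without DCIR2 array 2 (0.18) or with every probe set (0.138), range 0.000425 to 0.18 over the alternatives.

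The other T cell lists did not pass by camera. Of the anergy genes 4 of 18 rose and 5 fell, or 4 and 6 adjusted over the list alone, led by Dgka (log2 change -2.03) and Lag3 (1.34) (adjusted p = 0.384). Of the regulatory T cell genes 1 of 15 rose and 1 fell, or 1 and 1 adjusted over the list alone, namely Il2ra (2.33) and the semaphorin receptor Nrp1 (-0.93) (adjusted p = 0.975, median -0.07, mean 0.05). Nrp1 (-0.55 without PBS array 1) did not pass without PBS array 1 (adjusted p = 0.163), without DCIR2 array 1 (0.0513), without DCIR2 array 2 (0.211), with quantile normalization (0.0528) or with every probe set (0.119), range 0.00399 to 0.211 over the alternatives. Of the Th1 and cytotoxic effector genes 5 of 14 rose and 3 fell, or 5 and 3 adjusted over the list alone, led by Il18r1 (-2.81) and Tnf (2.20) (adjusted p = 0.259). Of the Th2 genes 1 of 7 rose and 0 fell, or 1 and 1 adjusted over the list alone, the 1 being Ccr8 (2.49) (adjusted p = 0.672). Of the Th17 genes 3 of 6 rose and 1 fell, or 3 and 2 adjusted over the list alone, led by the aryl hydrocarbon receptor Ahr (2.82-fold higher) and the cytokine gene Il17a (1.30) (adjusted p = 0.384). Of the T follicular helper genes 4 of 13 rose and 3 fell, or 4 and 3 adjusted over the list alone, led by Cd200 and Pou2af1 (2.08) (adjusted p = 0.838, median -0.17, mean 0.25). Of the cholesterol synthesis genes 4 of 16 rose and 0 fell, or 4 and 0 adjusted over the list alone, among them Idi1 (from 5.48 to 6.47 on the log2 scale). The list had a camera adjusted p of 0.0952 and passed without PBS array 2 (adjusted p = 0.0418) or without DCIR2 array 1 (0.00253), range 0.00253 to 0.644 over the alternatives.

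Of the apoptosis genes 5 of 13 rose and 2 fell, or 5 and 2 adjusted over the list alone, led by Gadd45b (log2 change 2.31) and the survival gene Bcl2l1 (1.26) (adjusted p = 0.434, median -0.05, mean 0.30). Bcl2l1 did not pass without DCIR2 array 2 (adjusted p = 0.0775), range 0.00232 to 0.0775 over the alternatives. Of the immediate-early stress genes 3 of 14 rose and 5 fell, or 3 and 5 adjusted over the list alone, led by Hsph1 (2.16) and Jun (-1.52) (adjusted p = 0.434). In the lists of B cell, neutrophil and erythroid markers 0 rose and 0 fell in limma (2, 1 and 0 at an unadjusted p under 0.05, all lower, and camera adjusted p = 0.384, 0.434 and 0.384). In those of CD8 T cell, plasma cell, dendritic cell, macrophage and monocyte, and stromal and endothelial markers 0 rose and 1 fell in each (adjusted p = 0.28, 0.384, 0.384, 0.313 and 0.384). For all 8 of these lists the counts adjusted over the list alone were the same. Of the 85 markers of other cells in the cell type lists, natural killer cells included, 0 rose and 9 fell after anti-DCIR2-BDC, with a median change of -0.16, and 0 rose and 6 fell after anti-DEC205-BDC. At an unadjusted p under 0.05, 0 were higher after either antibody.

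The third comparison set the antibodies against each other. They target different dendritic cell types, but any other difference between the antibodies, such as in antigen delivered, cannot be told apart from that. Il3, Zbtb32, the protease inhibitor gene Serpinb6b and the carboxypeptidase gene Cpd were higher after anti-DCIR2-BDC than after anti-DEC205-BDC, and these 4 were the only genes that passed in limma over all genes. Il3 was 21.1-fold higher, at 9.84 ± 0.69 against 5.44 ± 1.27 (SD, n = 2, log2 values). Zbtb32 was 3.66-fold higher, at 8.41 ± 0.35 against 6.54 ± 0.20, with a log2 difference of 1.87 and a 95% interval of 1.38 to 2.36. As the study chose Zbtb32 on these samples, its call is not independent evidence. Serpinb6b was 3.88-fold and Cpd 3.15-fold higher, and all 4 had an adjusted p of 0.0289. At an unadjusted p under 0.05 there were 2036 genes, where 996.9 would be reached by chance. The calls rest on few arrays: 0 genes passed in limma without DCIR2 array 1 and 0 without DCIR2 array 2 (1559 and 1314 at an unadjusted p under 0.05), 1 without DEC205 array 1, and 27 without DEC205 array 2. With no trend and with every probe set 0 passed in limma too (2185 genes and 2688 probe sets at an unadjusted p under 0.05). Il3 did not pass without DCIR2 array 1 (adjusted p = 0.162), without DCIR2 array 2 (0.291), with every probe set (0.52) or with no trend (0.0831), range 0.000318 to 0.52 over the alternatives. Zbtb32 did not pass without DEC205 array 1 (adjusted p = 0.195), without DCIR2 array 1 (0.162), without DCIR2 array 2 (0.291), with every probe set (0.491) or with no trend (0.0831), range 0.0141 to 0.491 over the alternatives. Serpinb6b did not pass without DEC205 array 1 (adjusted p = 0.176), without DCIR2 array 1 (0.162), without DCIR2 array 2 (0.262), with every probe set (0.493) or with no trend (0.0831), range 0.0141 to 0.493 over the alternatives. Cpd did not pass without DEC205 array 1 (adjusted p = 0.195), without DCIR2 array 1 (0.247), without DCIR2 array 2 (0.307), with every probe set (0.491) or with no trend (0.0831), range 0.0147 to 0.491 over the alternatives.

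**Figure D2:**
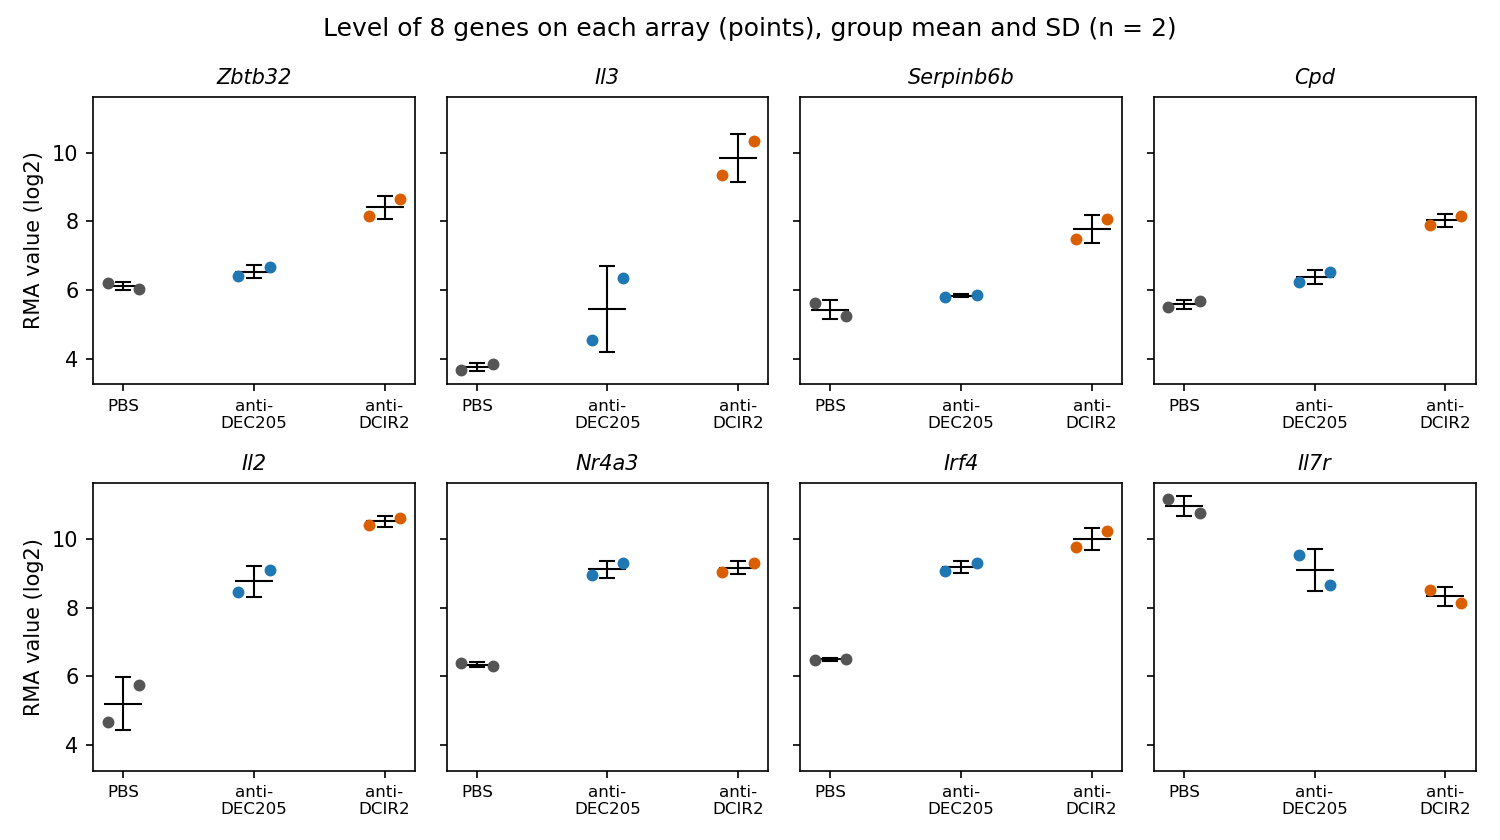
RMA values (log2) of 8 genes on each of the 6 arrays (points), with the group mean and SD (n = 2). Zbtb32 reached a mean of 8.41 after anti-DCIR2-BDC against 6.54 after anti-DEC205-BDC, while Nr4a3 reached 9.16 and 9.12.

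Of the genes next in order, which did not pass, the chemokine gene Ccl1 differed by 1.61 on the log2 scale (adjusted p = 0.0679) and Pdcd4, an inhibitor of translation, by -1.47 (adjusted p = 0.0717). Klhl24, the cortisone-activating enzyme gene Hsd11b1, Ifi203 and Syt11 differed by -1.39, -1.27, -1.19 and -1.09 (adjusted p = 0.122, 0.147, 0.147 and 0.147). Ccl1 passed without the dimmest 30% of genes (adjusted p = 0.0429) or without the dimmest 50% of genes (0.022), range 0.022 to 0.537 over the alternatives. Pdcd4 passed without DEC205 array 2 (adjusted p = 0.0284), without the dimmest 30% of genes (0.0435) or without the dimmest 50% of genes (0.0215), range 0.0215 to 0.544 over the alternatives. Klhl24 passed without the dimmest 50% of genes (adjusted p = 0.0497), range 0.0497 to 0.544 over the alternatives. Ly75 differed by -0.36 (adjusted p = 0.545) and Clec4a4 by 0.04 (adjusted p = 0.968).

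Of the members of the 9 lists that passed by camera between the antibodies, Il3 alone passed by itself over all genes. Ribosome biogenesis genes were higher (camera adjusted p = 9.33e-15, in the alternatives from 9.2e-16 to adjusted p = 0.186 with an estimated correlation), with a median difference of 0.48, and 11 of 27 passed adjusted over the list alone. Cell cycle genes were higher (camera adjusted p = 6.02e-10, in the alternatives from 6.99e-12 to adjusted p = 0.126 with an estimated correlation), with 5 of 34 adjusted over the list alone. So were amino acid uptake and one-carbon genes (camera adjusted p = 4.22e-08, in the alternatives from 8.57e-09 to adjusted p = 0.186 with an estimated correlation), with 3 of 15. Glycolysis genes were higher (camera adjusted p = 1.63e-05, in the alternatives from 8.66e-06 to adjusted p = 0.186 with an estimated correlation), with 2 of 13. Cytokine and chemokine genes were higher (camera adjusted p = 2.79e-07, in the alternatives from 1.03e-08 to adjusted p = 0.126 with an estimated correlation), with 6 higher and 1 lower of 23 adjusted over the list alone and Il2 at 1.75 (adjusted p = 0.166). Il2 passed with only the 4 arrays compared (adjusted p = 0.0468), range 0.0468 to 0.561 over the alternatives. Naive and quiescent genes were lower (camera adjusted p = 3.75e-07, in the alternatives from 1.89e-10 to adjusted p = 0.186 with an estimated correlation), with 5 of 21 adjusted over the list alone. T cell identity markers were lower (camera adjusted p = 1.88e-06, in the alternatives from 1.84e-09 to adjusted p = 0.186 with an estimated correlation), with 7 of 12 and Cd3g at -0.77 (adjusted p = 0.154). Anergy genes were lower (camera adjusted p = 0.0238, in the alternatives from 0.000602 to adjusted p = 0.318 with an estimated correlation), with 1 of 18 adjusted over the list alone, and did not pass without DEC205 array 1 (adjusted p = 0.129), without DCIR2 array 2 (0.0747) or by fry (0.11). Interferon response genes were lower (camera adjusted p = 0.0438, in the alternatives from 0.0143 to adjusted p = 0.261 with an estimated correlation), with 1 higher and 3 lower of 21 adjusted over the list alone, and did not pass without DEC205 array 2 (adjusted p = 0.19), without DCIR2 array 2 (0.121) or by fry (0.0996). By fry, chosen after the data were seen, 0 of the 28 lists passed, and 12 had an unadjusted p under 0.05, where camera gave 9 and 9. The counts are not like for like, as fry asks whether list members change at all and camera whether they change more than other genes. By fry the adjusted p of the 9 lists that camera called ran from 0.0544 (cell cycle) to 0.11 (anergy), short of the threshold.

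Activation genes did not pass (camera adjusted p = 0.203): Nr4a3 differed by 0.04 (adjusted p = 0.977), Nr4a1 by -0.17 (adjusted p = 0.841) and Tnfrsf9 by -0.78 (adjusted p = 0.255). Adjusted over the list alone, 2 of its 24 genes were higher and 1 lower. At an unadjusted p under 0.05, 6 were higher and 3 lower. Differences in the list ran from -0.78 to 1.09, with 14 above 0 and 10 below. Of the members of the 18 lists that follow, 0 passed by limma over all genes. Adjusted over the list alone and by camera, inhibitory receptors had 3 higher and 0 lower (adjusted p = 0.181), regulatory T cell genes 0 and 1 (0.142), Th1 genes 0 and 1 (0.572), Th2 genes 1 and 0 (0.266), Th17 genes 3 and 1 (0.142) and T follicular helper genes 1 and 2 (0.589). In the same terms, cholesterol genes had 0 and 0 (0.589), apoptosis genes 0 and 0 (0.672) and stress genes 0 and 0 (0.542). Macrophage, erythroid and stromal markers had 0 and 1 in each list (0.774, 0.142 and 0.542), and CD8 T cell, B cell, plasma cell, dendritic cell, natural killer and neutrophil markers 0 and 0 (0.589, 0.771, 0.672, 0.181, 0.247 and 0.203). At an unadjusted p under 0.05 there were 36 of the 192 genes in these 18 lists. Median and mean differed in sign for the cholesterol (0.00121 and -0.07), B cell (0.05 and -0.05) and macrophage lists (0.01 and -0.04), all of which camera put below other genes. The regulatory T cell list passed without DCIR2 array 1 (adjusted p = 0.0384) or with quantile normalization (0.043), range 0.0384 to 0.629 over the alternatives. The Th2 list passed without DEC205 array 1 (adjusted p = 0.0174), range 0.0174 to 0.948 over the alternatives. The Th17 list passed without DCIR2 array 2 (adjusted p = 0.035) or without the dimmest 30% of genes (0.0451), range 0.035 to 0.383 over the alternatives. The stress list passed without DEC205 array 2 (adjusted p = 0.0185), range 0.0185 to 0.809 over the alternatives, the cholesterol list without DCIR2 array 2 (adjusted p = 0.00999), range 0.00999 to 0.852 over the alternatives and the erythroid list without DEC205 array 2 (adjusted p = 0.0456), range 0.0456 to 0.383 over the alternatives.

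Set side by side, the changes after the antibodies ran in parallel. Il2, Irf4, Bcat1, Cdca7, Mrto4 and Mfsd2a were among the 10 largest rises under the naming rule after both, and Il7r, Il18r1, Tmem71 and Snord61 among the 10 largest falls. Across the 19938 genes, which are not independent replicates, the log2 changes against PBS correlated at Pearson r = 0.902 and Spearman rho = 0.798, where unchanged groups simulated against the same PBS arrays gave a mean r of 0.50. The covariance was 0.222, against 0.0171 in the simulation, a difference of 0.205. The sign was the same for 78.4% of genes, against 66.7% in the simulation. Both comparisons called 1658 genes in the same direction, 1011 higher and 647 lower, where independent lists would share 107 and 55.0. The simulations shared at most 2, but they held no changed genes. They therefore cannot show how many of the shared calls come from the shared controls. By limma 0 genes were called in opposite directions, and 4 had unadjusted p-values under 0.05 in opposite directions. As both comparisons use the same 2 PBS arrays, part of the excess over independent lists may come from the shared controls. The number of genes called in both was 983 without PBS array 1, 1056 without DEC205 array 1 and 905 without DEC205 array 2.

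Of the genes called after anti-DEC205-BDC, 94.0% were called after anti-DCIR2-BDC, which left 105 called in the former comparison and not in the latter, against 1910 the other way round. Among the 1060 that rose after anti-DEC205-BDC, 937 (88.4%) had a larger change after anti-DCIR2-BDC, and the median went from 1.04 to 1.42. Among the 703 that fell, 546 (77.7%) did so, with medians of -0.91 and -1.17. Il3 had a log2 change of 1.69 after anti-DEC205-BDC (limma adjusted p = 0.0574) against 6.09 after anti-DCIR2-BDC. In the former the change was 2.58 without DEC205 array 1. There Il3 passed in limma without the dimmest 30% of genes (adjusted p = 0.0401) or without the dimmest 50% of genes (0.025).

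**Figure D3:**
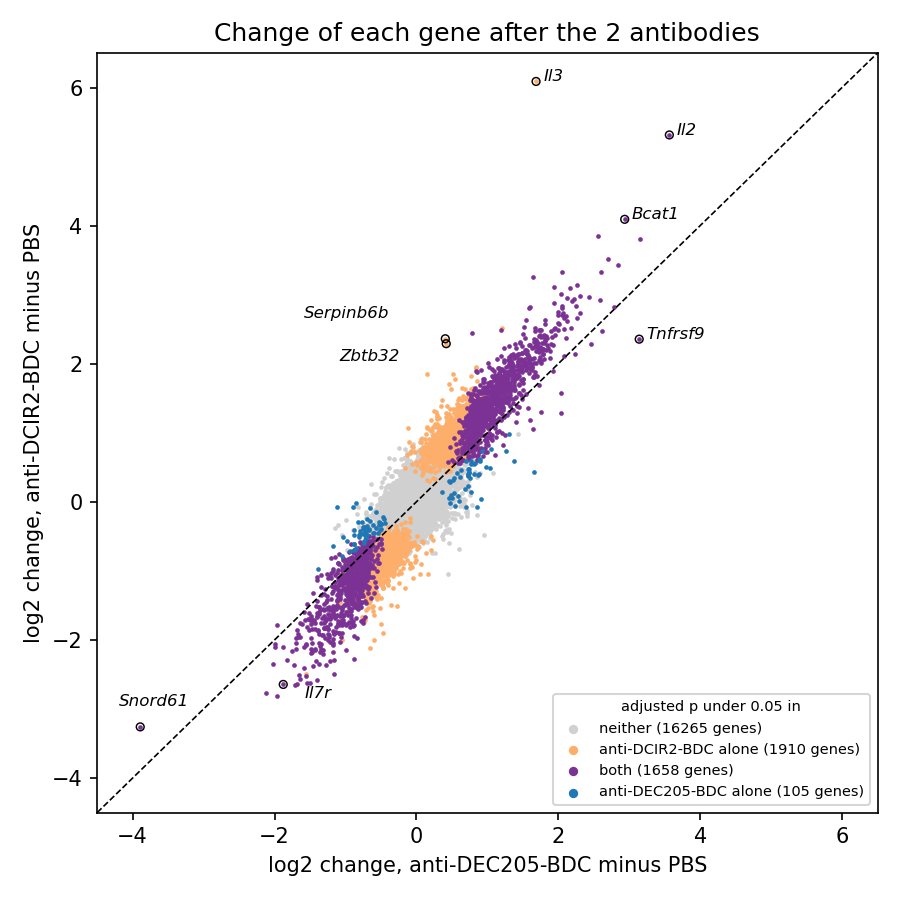
Log2 change of each of the 19938 genes after anti-DEC205-BDC (horizontal) and after anti-DCIR2-BDC (vertical), both against PBS, coloured by the comparison in which the adjusted p was under 0.05; the dashed line marks equal changes. Of the 1060 genes that rose after anti-DEC205-BDC, 937 lie above the line, and Il3 lies farthest above it among the genes named.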

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

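The tests of a constant share of responding cells, of 1 PBS array, of myeloid cells and of admixture were chosen only after the results were seen. Among the 13767 probe sets without exactly 1 gene symbol, which no comparison used, 199 passed after anti-DEC205-BDC (132 higher, 67 lower) and 943 after anti-DCIR2-BDC (481 higher, 462 lower), a signal in data not otherwise reported.

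Changes were larger after anti-DCIR2-BDC than after anti-DEC205-BDC for 88.4% of the genes that rose and 77.7% of those that fell after anti-DEC205-BDC, which argues against an offset between arrays, since that would enlarge changes of 1 direction only. A constant lower share of responding cells after anti-DEC205-BDC may account for the pattern: with 1 mixing fraction of the PBS and anti-DCIR2-BDC levels, fitted at 0.653, 0.028% of 3568 genes departed, within the bound of 5% written for the test, and the 1 gene was Il3 (adjusted p = 0.0378). Short of the threshold in that test, Zbtb32, Serpinb6b and Cpd differed from the fitted log2 level by -1.40, -1.48 and -1.18 (adjusted p = 0.0561, 0.0561 and 0.0658). Tnfrsf9 differed by 1.26 the other way (adjusted p = 0.0658). These genes were picked after their values were seen. That test sees large differences only: in simulations 0%, 1.04% and 15.4% departed when genes had fractions of 0.65, of 0.45 or 0.85, and of 0.3 or 0.95. In further looks taken after that result, with no bound set, the median fraction of falling genes exceeded that of rising genes by 0.187 (0.115 to 0.252 on leaving out each array), or by 0.121 (0.0528 to 0.205) among genes with a mean above 8. The gap was 0.00968 in 1 simulated data set with 1 fraction, which called 5578 genes against 3568 in the real data. With the 2 pairs of fractions above, given to genes whatever their direction, it was 0.0418 and 0.0720. Fractions unrelated to direction thus also left a gap. List medians ran from 0.101 (Th17, 4 genes) to 0.890 (interferon, 14 genes), so 1 fraction for all genes is in doubt but not excluded. A different response to the dendritic cell types, which the design names, stays open and untested.

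Interferon response genes were lower in both antibody groups, with 13 and 14 of 21 falling, and the list's calls were lost with an estimated correlation (adjusted p = 0.0563 and 0.0574). Against either PBS array alone the weaker median change of the list was -0.873, which argues against 1 unusual PBS array. After median centring it was -0.780. As the array medians lay between 5.43 and 5.56, an offset of whole arrays was too small for such a fall, and centring could not have removed it. A smaller share of dendritic cells and macrophages stays open, although the sort on CD4 and Thy1.1 would remove them: the lower median change of their 28 markers, Ly75 left out, was -0.148, but 22 of them lay below the median PBS level of genes, where a fall is understated. The 6 brighter ones, Cst3, Cd68, Cd74, H2-Eb1, C1qa and Zbtb46, had medians of -0.04 after anti-DEC205-BDC and -0.31 after anti-DCIR2-BDC, and by limma 0 and 0 of them passed (0 and 2 at an unadjusted p under 0.05). A batch shared by the 2 PBS arrays cannot be told apart from the PBS group, as no label separates them, and an effect of the antigen, which the design names, stays open beside it.

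Of the genes of the CD3 chains, Cd3g, Cd3d and Cd3e fell after anti-DCIR2-BDC, by 1.24, 1.03 and 0.74 on the log2 scale, and Cd247 had a change of -0.34 (adjusted p = 0.396). After anti-DEC205-BDC the first 3 had changes of -0.47, -0.48 and -0.40 (adjusted p = 0.0701, 0.0645 and 0.0707), and Cd3g passed with quantile normalization (adjusted p = 0.0401) or without the dimmest 50% of genes (0.0417), range 0.0401 to 0.319 over the alternatives, Cd3d with quantile normalization (adjusted p = 0.0276) or without the dimmest 50% of genes (0.037), range 0.0276 to 0.287 over the alternatives, and Cd3e without DCIR2 array 1 (adjusted p = 0.0455), without DCIR2 array 2 (0.048), with quantile normalization (0.019) or with only the 4 arrays compared (0.0427), range 0.0161 to 0.308 over the alternatives. They belong to the wider list of T cell identity markers, in which 8 of 12 fell after anti-DCIR2-BDC, or 9 adjusted over the list alone (camera adjusted p = 0.000116, in the alternatives from 5.23e-07 to adjusted p = 0.212 with an estimated correlation), and 1 fell after anti-DEC205-BDC, or 5 adjusted over the list alone (camera adjusted p = 0.0236, in the alternatives from 0.00187 to adjusted p = 0.408 with an estimated correlation), where the list did not pass without PBS array 2 (adjusted p = 0.174), without DEC205 array 2 (0.0882), without the dimmest 30% of genes (0.0533), without the dimmest 50% of genes (0.0579), with no trend (0.0526) or by fry (0.115). Admixture of other cells is argued against by 0 of 85 markers of other cells rising in limma after anti-DCIR2-BDC, 0 at an unadjusted p under 0.05, in cells sorted on CD4 and Thy1.1, and a fall shared by all bright probe sets by that wider list's median of -0.78, at percentile 0.05 among 10000 random lists matched on mean level. An effect of the antigen, which the design names, stays open and untested.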

How the results depend on the processing

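The use of fry was chosen after the data were seen. Leaving out each array in turn gave 997 to 1367 changed genes after anti-DEC205-BDC, 2090 to 3637 after anti-DCIR2-BDC and 0 to 27 between the antibodies. It gave 10 to 11, 10 to 12 and 9 to 10 changed lists, a correlation of the responses of 0.820 to 0.912, and 905 to 1216 genes called in both. Where 1 array was left in a group, it was assumed to vary like the others. Between the antibodies 7 genes passed without the dimmest 30% and 9 without the dimmest 50%, where fewer genes were tested. By limma 0 passed with no trend and 0 with every probe set (2185 genes and 2688 probe sets at an unadjusted p under 0.05). Every probe set gave 694 after anti-DEC205-BDC. A minimum of 2-fold left 827 and 1839 genes by construction. With the estimated correlation 0, 0 and 0 lists passed by camera (8, 8 and 7 at an unadjusted p under 0.05), and with fry 10, 11 and 0 (12, 14 and 12 unadjusted). A higher correlation did not cost cell cycle, cytokine and interferon genes their calls, as their estimates lay below the preset. For lists with estimates above it, the cause of the lost calls was not tested. With the replicate number as a block, 2069, 3885 and 2 genes passed. Zbtb32 and Serpinb6b between the antibodies and the inhibitory receptor list after anti-DCIR2-BDC then did not pass, while Il3, Cd3d and Cd3e after anti-DEC205-BDC and Cst3 after anti-DCIR2-BDC, among others, did. Deviations of arrays with equal numbers correlated at 0.145, 0.131 and 0.0714. Median centring moved the median change of all genes from -0.05 to 0.06 after anti-DCIR2-BDC, and results are given without it. Of 558 alternative values of called lists 63 no longer passed, of 951 of lists not called 18 passed, of 3107 of named genes that were called 111 no longer passed, of 2473 of those not called 39 passed, and 0 called values changed direction. The neutrophil list had no member left without the dimmest 50%, so it has no value there. Dim genes lie near the floor of the arrays, where changes are understated.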

Other observations

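Further gene families were chosen after their values were seen, so their counts describe these arrays and test nothing. After anti-DCIR2-BDC 17 of 18 aminoacyl-tRNA synthetase genes, which charge tRNAs for protein synthesis, rose, led by Iars (log2 change 2.11). All 8 genes of the chaperonin CCT, which folds actin and tubulin, rose, led by Cct3 (2.42), as did 12 of 14 core proteasome genes, 50 of 74 mitochondrial ribosomal protein genes and 14 of 18 nuclear pore genes, with Nup43 (2.69) in front. Of the purine and pyrimidine synthesis genes 11 of 12 rose, led by Ctps (2.71), and both polyamine synthesis genes measured rose, Srm by 3.10 and Odc1 by 1.42. After anti-DEC205-BDC the counts of genes that rose were 12, 8, 9, 31, 8, 10 and 2 in the same order.

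Members of other families fell. After anti-DCIR2-BDC these were 5 of 8 Gimap genes, lymphocyte GTPases led by Gimap6 (-1.52), 6 of 10 genes of the Ifi200 family, led by Ifi203 (-2.59), and 7 of 7 guanylate-binding protein genes, led by Gbp4 (-2.37), and after anti-DEC205-BDC 3, 5 and 6.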
